A study of Dermatophagoides pteronyssinus with 3 samples.

How the data were processed

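RNA of the house dust mite Dermatophagoides pteronyssinus was separated on a gel, and 3 bands were sequenced as 1 library each. Band 1 held RNA longer than 500 bp, band 2 RNA of about 300 bp and band 3 RNA of 50 to 150 bp. Per the labels' protocols, the RNA came from a standard commercial mite culture, was extracted with Trizol, and about 100 ng of each band entered a total RNA library kit with a ribosomal RNA depletion step (KAPA with RiboErase HMR, made for human, mouse and rat ribosomal RNA). Sequencing was on an Illumina HiSeq instrument, per the series' design text. The submitters' processing notes name bcl2fastq and Bowtie2, without versions. Contig names have the form that the Trinity assembler writes. The assembler's settings, the read filters, the tool that made the tables and the handling of reads that match several contigs are not given in the sources used here.

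The authors deposited 1 table per library, with 1 line per contig. Per the file headers, it gives the contig's length, the count of reads on it, the sum of aligned bases, the mean coverage, the RPKM (reads per 1000 bases of contig and 1000000 reads), the number of covered bases and the covered percent of the contig. The deposited RPKM were recomputed from the read counts, the length and the sum of reads over the same table; the largest difference was 0.0118% of the value among contigs with at least 100 reads. Mean coverage is thus not scaled by library size, while RPKM is scaled by the reads placed on listed contigs and leaves out reads placed on none. The number of such unplaced reads is not known here. The mean aligned length per read was 100.2, 100.1 and 99.7 bases in bands 1, 2 and 3. The shortest listed contig had 151 bases in each of the 3 tables, so RNA that could only assemble into shorter contigs is outside these values.

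Contigs carry names of the form gene and isoform within a component, where a component is a set of contigs that Trinity built from connected sequence. The 3 tables were made from separate contig sets. A contig name found in both bands 1 and 2 (5710 names) had the same length in 25 cases, against 24.2 expected when lengths are paired at random. For bands 1 and 3 the values were 14 of 3137 names against 18.0, and for bands 2 and 3 they were 32 of 4936 against 37.9. A contig of one band was therefore not matched to a contig of another, and planned comparisons that need such a match were not made: shared contigs, the correlation of abundance between bands, and contigs 4-fold apart. The tables used here give contig names and no sequence or gene name, so contigs were not placed on a genome or assigned to genes or RNA classes. The reference gene table was not used for that reason.

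Each library was described by the number of contigs with at least 10 reads, the share of reads on the 10 contigs with most reads, the read-weighted median contig length over contigs with at least 10 reads, and Spearman's rho of contig length with mean coverage across contigs. The shares of reads on contigs over 500 and over 1000 bases, and sums over the contigs of a component, were added after the data were examined. The contigs to be named were fixed before the data were examined as the 10 with most reads per library; since they carry no gene names, the text names a few and summarises the rest. The components, the longest contig of band 3 and the contigs with the highest coverage were named after their values were seen. Parts of that rule that need a match between bands or gene names gave no contigs. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

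With 1 library per band there is no replicate error, so no significance test between bands was made and no p-value is given; the ratios and differences between bands compare single libraries. Total reads on listed contigs were 99600344, 60134651 and 38218991 in bands 1, 2 and 3. At this depth the exact (Clopper-Pearson) 95% interval of a share of reads is at most 0.0159 percentage points to either side for the shares of all placed reads of a library given below; shares of a total without its highest contig or component have fewer reads and were given no interval. A count of 0 reads on a contig allows, at 3 counts, up to 0.0301, 0.0499 and 0.0785 reads per 1000000 placed reads (RPM) in bands 1, 2 and 3. These intervals and floors cover counting error only: reads without molecular identifiers are not independent molecules, and differences between gel runs or library preparations are not in them. The statistics were tested on simulated data drawn from each library with 200 contigs raised 4-fold. Shares, counting the share of reads that thinning kept, came back within 0.0910, 0.0684 and 0.00888 percentage points for the 29244, 9996 and 8604 contigs of bands 1, 2 and 3. The weighted median length came back exactly. The draws treat reads as independent, so this checks the computation only. Alternatives were other read minimums, a length filter, mean coverage in place of reads, other numbers of top contigs, totals without the highest contig or component, and thinning to the shallowest library. To show what a read minimum does to rho, coverage was shuffled over the contigs above 0 reads, reads were set to coverage times length over the mean aligned length per read, and the minimum was applied to these.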

Results

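The series examined which RNA is present in 3 gel bands of RNA from the house dust mite Dermatophagoides pteronyssinus, a common source of indoor allergens. The submitters call this RNA immunogenic. Each band gave 1 total RNA sequencing library and its own set of assembled contigs, that is, sequences rebuilt from overlapping reads. Band 1 (longer than 500 bp) had 99600344 reads on 29244 listed contigs. Band 2 (about 300 bp) had 60134651 reads on 9996 contigs, and band 3 (50 to 150 bp) had 38218991 reads on 8604 contigs. The contigs summed to 10010359 bases in band 1, 2623846 bases in band 2 and 2025495 bases in band 3. There were no replicates, so the differences below have no replicate check and describe these 3 libraries.

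The first comparison concerned how many contigs each band yielded and how well reads backed them. Contigs with at least 10 reads numbered 11451 in band 1, 3014 in band 2 and 3124 in band 3. Band 1 thus had 3.80 times as many as band 2 and 3.67 times as many as band 3, from 1.66 and 2.61 times as many reads. Strongly covered contigs had another order. Those with a mean coverage of at least 1000 numbered 359 in band 1, 387 in band 2 and 578 in band 3. Band 3 had the fewest reads, but its contigs also summed to the fewest bases, 2025495 against 10010359 in band 1. Contigs with fewer than 10 reads made up 60.8%, 69.8% and 63.7% of the contigs in bands 1, 2 and 3, and together held 0.0942%, 0.0593% and 0.0700% of the reads. The median contig had 7 reads in band 1 and 6 reads in bands 2 and 3, at a median coverage of 3.04, 2.70 and 3.08. No read was placed on 105 contigs of band 1, 8 of band 2 and 16 of band 3. Every base was covered in 84.0%, 89.8% and 72.1% of the listed contigs of bands 1, 2 and 3. The number of contigs per band depended on the minimum and the depth. With at least 100 reads required it was 1592, 790 and 1393, and with bands 1 and 2 thinned to the reads of band 3 it was 4925 and 1904 against 3124 (at least 10 reads) and 855 and 706 against 1393 (at least 100 reads), so at the higher minimum band 1 was below band 3.

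The second comparison concerned how far a few contigs dominated each band. A small number of contigs held most of the reads in every library, and by single contigs band 1 was the most concentrated. The 10 contigs with most reads held 47.3% of the reads in band 1, 32.3% in band 2 and 31.8% in band 3. The difference from band 1 to band 2 was 15.04 percentage points and to band 3 15.53 percentage points, and bands 2 and 3 differed by 0.49 percentage points. The counting error of these shares was at most 0.0148 percentage points to either side (exact 95% interval). To reach 50% of the reads took 12 contigs in band 1, 21 in band 2 and 28 in band 3. To reach 90% took 93, 119 and 217 contigs, and to reach 99% took 318, 329 and 734. The top 100 contigs held 91.0%, 87.0% and 76.3% of the reads. Bands 2 and 3 were close for the top 10 contigs by reads. With mean coverage in place of reads they were further apart (29.6% against 21.9%), while band 1, at 32.6%, had a smaller lead over band 2. With the highest contig left out, the next 10 contigs held 30.4% of the remaining reads in band 2 and 26.9% in band 3. Summed per Trinity gene, the top 10 held 63.1%, 50.3% and 59.4% in bands 1, 2 and 3.

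**Figure D1:**
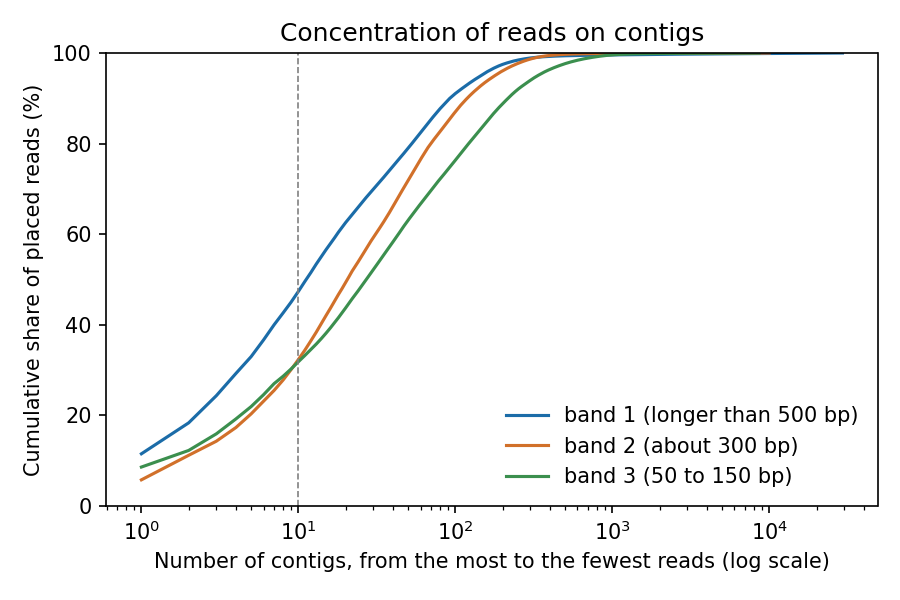
Cumulative share of placed reads (%, vertical axis) against the number of contigs taken from the most to the fewest reads (log scale), 1 line per band; the dashed line marks 10 contigs. At 10 contigs band 1 stood at 47.3%, band 2 at 32.3% and band 3 at 31.8%, and at 100 contigs they stood at 91.0%, 87.0% and 76.3%.

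The contig with most reads in band 1 was TRINITY_DN10368_c51_g1_i1, with a length of 4541 bases. It held 11417037 reads, 11.5% of the library, at an RPKM of 25243. Next was TRINITY_DN10360_c24_g3_i3 (1756 bases), with 6.84% of the reads. All of the top 10 contigs of band 1 were longer than 500 bases, from 561 to 4541 bases, and 7 of them were longer than 1000 bases. In band 2 the pair with most reads were TRINITY_DN2553_c0_g2_i4 (559 bases) and TRINITY_DN2553_c0_g2_i1 (553 bases), which are isoforms of one Trinity gene. They held 5.71% and 5.42% of the reads. The top 10 contigs of band 2 ran from 168 to 860 bases, and 5 of them were longer than 500 bases. In band 3 the highest contig was TRINITY_DN3414_c60_g2_i3, with a length of 3171 bases, all of them covered. It held 3261968 reads, 8.53% of the library, at an RPKM of 26916. The top 10 contigs of band 3 ran from 196 to 3171 bases. Of these, 7 were longer than 1000 bases, and these 7 were also the ones that belonged to the component TRINITY_DN3414_c60. None of the top contigs carries a gene name in the tables, so whether they are ribosomal, messenger or other RNA was not analysed here.

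**Figure D2:**
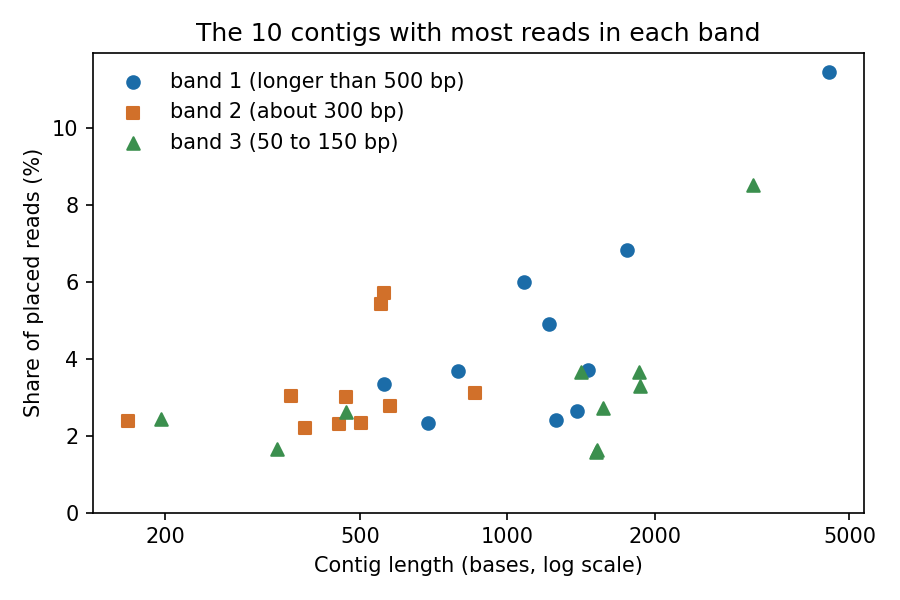
Length (bases, log scale) and share of placed reads (%) of the 10 contigs with most reads in each band, 1 point per contig. The highest points are a contig of 4541 bases with 11.5% in band 1, one of 3171 bases with 8.53% in band 3, and one of 559 bases with 5.71% in band 2.

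Contigs of one component may share sequence, which could not be checked without the sequences. How reads that match several of them were divided is not given in the sources used here. Component sums do not depend on that division within a component. The component TRINITY_DN3414_c60, with 17 contigs of 180 to 3171 bases, held 30.1% of the reads of band 3. The highest component of band 1, TRINITY_DN10360_c24, had 8 contigs of up to 1756 bases and held 22.4% of the reads. TRINITY_DN10311_c3 (23 contigs of up to 793 bases) followed in band 1 with 15.28%, and TRINITY_DN10368_c51 (5 contigs of up to 4541 bases) with 14.97%. In band 2 the highest were TRINITY_DN2553_c0, with 6 contigs of up to 559 bases and 11.9% of the reads, and TRINITY_DN2597_c13, with 14 contigs of up to 576 bases and 11.5%. The second component of band 3, TRINITY_DN3406_c24, had 25 contigs of up to 1396 bases and 12.4% of the reads. The 10 highest components held 79.4% of the reads in band 1, 67.8% in band 2 and 75.0% in band 3. By components, 50% of the reads was reached with 3 in band 1, 6 in band 2 and 3 in band 3. Bands 2 and 3 thus differed by component (67.8% against 75.0%) where they were close by single contig (32.3% against 31.8%). At higher shares their order turned: 90% of the reads took 26 components in band 2 and 31 in band 3, and 99% took 61 and 118.

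The third comparison concerned contig length against the size of the gel fraction. Counted by contig, length followed the order of the fractions, and the numbers of reads on listed contigs fell in the same order. Fraction and sequencing depth can therefore not be told apart as sources of this order. The median contig had 231 bases in band 1, 206 in band 2 and 188 in band 3, and contigs over 500 bases made up 13.4%, 5.77% and 4.39%. Contigs of at most 200 bases were 35.9% of the contigs of band 1, 46.7% of band 2 and 58.8% of band 3. The shortest length listed in any band was 151 bases, so none of the listed contigs of band 3 was as short as its gel fraction. The longest contigs had 8490 bases in band 1, 7144 in band 2 and 8043 in band 3. The one in band 3, TRINITY_DN3266_c0_g1_i1, was covered over its full length at a mean coverage of 202.5.

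Counted by reads, the order was different: band 3 had longer contigs than band 2. The read-weighted median contig length was 1041 bases in band 1, 395 in band 2 and 487 in band 3. Contigs over 500 bases held 68.6% of the placed reads in band 1, 37.2% in band 2 and 49.6% in band 3. Contigs over 1000 bases held 50.2%, 3.77% and 35.3%, whereas the share on contigs over 300 bases was 77.5% in band 1, 64.6% in band 2 and 64.8% in band 3. Reads of band 2 lay mostly on contigs of 300 to 1000 bases: the class over 300 and up to 500 bases held 27.4% and the class over 500 and up to 1000 bases held 33.4%. In band 3 the class over 1000 and up to 2000 bases, made of 41 contigs, held 26.2% of the reads, and the 6 contigs over 2000 bases held 9.02%. By the share over 500 bases and the weighted median, the order of bands 2 and 3 rested on the highest components. Without the highest component of each library, contigs over 500 bases held 61.7% of the reads in band 1, 29.6% in band 2 and 28.7% in band 3, and the read-weighted medians were 793, 379 and 317 bases. Both were also reversed with mean coverage in place of reads, which removes the weight that long contigs gain from their length. Contigs over 500 bases held 29.4%, 17.8% and 16.3% of the summed coverage, and the coverage-weighted medians were 266, 243 and 202 bases. On contigs over 1000 bases band 3 stayed above band 2, with 43.4%, 4.28% and 11.01% of the reads in bands 1, 2 and 3 without the highest component and 15.1%, 0.870% and 7.95% by coverage.

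**Figure D3:**
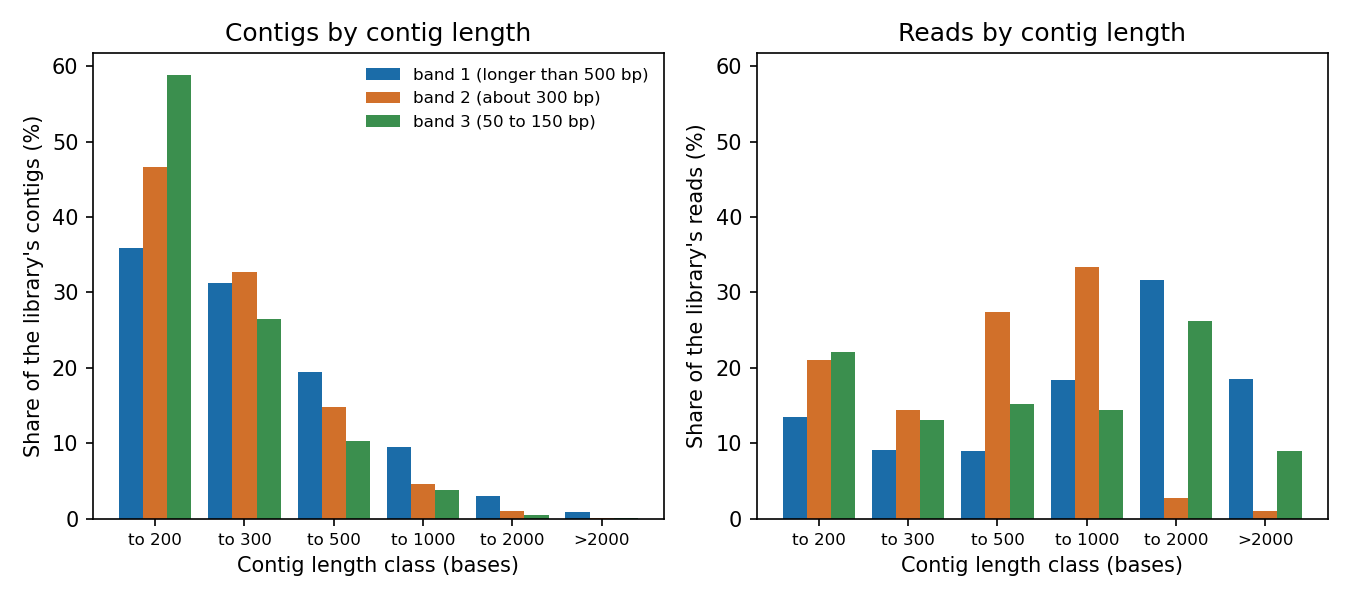
Share of the contigs (left, %) and of the reads (right, %) of each library by contig length class in bases, each class running from above the previous limit to the limit shown; bars are single libraries with no error bars, blue for band 1, orange for band 2 and green for band 3. Contigs up to 200 bases made up 58.8% of the contigs of band 3, while contigs over 1000 and up to 2000 bases held 26.2% of its reads against 2.71% in band 2.

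The contig with the highest mean coverage was TRINITY_DN10311_c3_g3_i9 in band 1 (193 bases, RPKM 100772), TRINITY_DN2585_c0_g3_i1 in band 2 (168 bases, RPKM 142242) and TRINITY_DN3365_c1_g3_i1 in band 3 (196 bases, RPKM 124601). They held 1.94%, 2.39% and 2.44% of the reads. Of the 10 contigs with most reads, 3 in band 1, 6 in band 2 and 3 in band 3 were also among the 10 with the highest coverage. Across contigs with at least 10 reads, Spearman's rho of length with coverage was 0.08 in band 1, -0.29 in band 2 and -0.29 in band 3. With every contig above 0 reads it was 0.47, 0.28 and 0.20, so the sign in bands 2 and 3 turned with the read minimum. In band 1 it turned to -0.69 with a minimum of 100 reads. The read minimum itself moves rho: with coverage shuffled over the contigs of each band (200 times), the mean rho was near 0 with no minimum, -0.61, -0.66 and -0.47 with a minimum of 10 reads, and -0.58, -0.13 and -0.11 with a minimum of 100 reads. The sign of rho at a minimum is therefore no measure of whether long contigs had lower coverage. Apart from band 3 at 100 reads, however, the minimum alone did not give the observed values. At 10 reads they lay above the highest of the shuffles (-0.587, -0.632 and -0.435). At 100 reads the observed -0.694, -0.291 and -0.1843 lay below the lowest (-0.621, -0.248 and -0.1834), in band 3 only just. Contigs are not independent replicates, and these values describe single libraries.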

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

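Every result rests on 1 library per band, so no replicate could be left out, and no paired analysis was possible because no band has a second library. Chosen after seeing the data were both thinning settings, the sums per component, the coverage-weighted and left-out settings for contig length, the correlation with no minimum, and the shares over 500 and 1000 bases with all their settings. Values are for bands 1, 2 and 3. The number of contigs was 11451, 3014 and 3124 with at least 10 reads. It became 29139, 9988 and 8588 with no minimum, 1592, 790 and 1393 with a minimum of 100 reads, and 3889, 579 and 379 among contigs of at least 500 bases. Thinning to the reads of band 3 gave 4925 and 1904 for bands 1 and 2 with at least 10 reads, and 855 and 706 against 1393 with at least 100. Band 1 was highest in each setting except the last, where band 3 was, and bands 2 and 3 changed order with no minimum and with the length filter. The share of the top 10 contigs was 47.3%, 32.3% and 31.8%. With mean coverage in place of reads it was 32.6%, 29.6% and 21.9%. With the highest contig left out of both the top 10 and the total, it was 43.0%, 30.4% and 26.9%. For the top 1 contig it was 11.5%, 5.71% and 8.53%, and for the top 100 it was 91.0%, 87.0% and 76.3%. Summed per component it was 79.4%, 67.8% and 75.0%. Band 1 was highest in each of these settings, and band 3 passed band 2 for the top contig and per component. For the single highest unit, the order changed once contigs were summed. The top 1 Trinity gene held 12.2%, 11.7% and 17.6%, and the top 1 component 22.4%, 11.9% and 30.1%, so band 3 was highest there. The read-weighted median length of 1041, 395 and 487 bases did not move with a minimum of 100 reads. It was 403, 327 and 241 unweighted, 266, 243 and 202 weighted by coverage, 776, 386 and 460 without the highest contig, and 793, 379 and 317 without the highest component. Contigs over 500 bases held 29.4%, 17.8% and 16.3% of the summed coverage. Their share of reads was 64.5%, 33.4% and 44.9% without the highest contig, and 61.7%, 29.6% and 28.7% without the highest component. Contigs over 1000 bases held 50.2%, 3.77% and 35.3% of the reads, and 15.1%, 0.870% and 7.95% of the summed coverage. Their share of reads was 43.7%, 3.995% and 29.2% without the highest contig, and 43.4%, 4.28% and 11.01% without the highest component. Band 3 was above band 2 in each. The correlation of length with coverage (0.08, -0.29 and -0.29) was -0.69, -0.29 and -0.18 with a minimum of 100 reads and 0.47, 0.28 and 0.20 with no minimum. The minimum alone moves it: with coverage shuffled over contigs, also chosen after seeing the data, the mean rho was -0.61, -0.66 and -0.47 at 10 reads and -0.58, -0.13 and -0.11 at 100 reads. The observed values lay above all 200 shuffles at 10 reads and below all of them at 100 reads. In band 3 at 100 reads the gap was too small to decide (-0.1843 against a lowest of -0.1834). The minimum alone did not give the other values. Of the 30 contigs with most reads, 27 had a lower share by coverage and 3 a higher one. Shared contigs, the correlation between bands, contigs 4-fold apart and RNA classes gave no value, since contigs could not be matched or named. Most contigs of each band had fewer than 10 reads.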

Other observations

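The test of contigs per gene over all genes was set before its result was seen; the other tests here were chosen after the values they use were seen. Genes in the sense of the assembler, that is, groups of contigs taken as isoforms, numbered 26209 in band 1, 9081 in band 2 and 6304 in band 3. Band 3 had 1.365 contigs per gene, against 1.116 in band 1 and 1.101 in band 2, and 9.04% of its genes had more than 1 contig, against 5.40% and 4.11%. The gene with most contigs had 57 in band 1, 25 in band 2 and 33 in band 3. Genes with at least 1 read per 1000000 placed reads (1 RPM) were 9.85% of the genes of band 3, 4.25% of band 1 and 4.85% of band 2. Among the genes with at least 1000 RPM, the mean number of contigs was 6.89 in band 3, 5.47 in band 1 and 4.31 in band 2.

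One hypothesis for the contigs per gene is that band 3 only has more strongly covered genes, which tend to be split into more contigs. Weighted to one spread of genes over 7 classes of RPM, band 3 stood at 1.02 times the higher of the other bands, so over all genes this may account for the difference. Most of that weight lies on genes below 1 RPM, with class means of 1.00 to 1.25 contigs in all bands. The ratio of 1.02 therefore says little about strongly covered genes. Over the 4 classes from 1 RPM the ratio was 1.23, and band 3 was above both other bands in each class. With 1 library per band this has no replicate check, which leaves open whether more variants of the same sequences were present or assembled in band 3. Reads placed on the contigs of band 3 were 0.636 times those of band 2, but the number of unplaced reads is not known, so an effect of sequencing depth stays open.

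A second pattern is that 49.6% of the placed reads of band 3, cut from the gel at 50 to 150 bp, lay on contigs over 500 bases. Reads of RNA that assembled only into contigs shorter than those listed are not in this total. Their number is unknown, so the share among all reads of band 3 is not known. The shortest listed contig of band 3 had 151 bases, so none has a length within the stated sizes of the fraction; this restates the lengths and is no test of how the contigs arose. Longer RNA carried into the gel slice and short fragments of longer RNA joined by the assembler cannot be told apart, since the tables give no positions of read ends. The share of contigs over 500 bases (at least 10 reads) with every base covered was 58.4% in band 3, 66.5% in band 1 and 68.8% in band 2. Band 3 was thus lower than both, with differences of -8.13 percentage points from band 1 and -10.39 from band 2, which decides neither. The excess of band 3 over band 2 on contigs over 500 bases was gone without the highest component of each library, with band 3 minus band 2 at -0.91 percentage points. The component left out was far ahead only in band 3 (30.1% of the reads, the next 12.4%). In band 2 it held 11.9%, close to the next at 11.5%. On contigs over 1000 bases, 35.3% in band 3 against 3.77% in band 2 became 11.01% against 4.28% without these components. The remaining 6.73 percentage points argue against the highest component, as the assembler drew it, as the whole cause. Whether other components hold parts of the same RNA is not known without sequences. What TRINITY_DN3414_c60 is would be the first thing to look up in the sequences.

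Another pattern is the larger number of contigs in band 1 than in band 3. For contigs with at least 10 reads, depth of the counted reads alone is argued against as the whole cause, since band 1 thinned to the reads of band 3 still had 1.58 times as many. With at least 100 reads, 1592 contigs in band 1 against 1393 in band 3 became 0.614 times as many as in band 3 after thinning, so depth may account for that smaller excess. Contigs with a mean coverage of at least 1000 were fewer in band 1 (359) than in band 3 (578). The contigs themselves were assembled before thinning, so an effect of depth on the assembly may remain. A wider range of RNA in the fraction longer than 500 bp also stays open and was not tested. The design names only the size of the fractions.

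Read numbers per contig were more often even than odd: 58.2%, 66.8% and 65.5% of the contigs above 0 reads in bands 1, 2 and 3 had an even number. The most common number was 4 reads, found for 5185, 2797 and 2075 contigs, against 1921, 654 and 633 contigs with 3 reads and 2507, 762 and 492 with 5. If both reads of a pair were counted, which the sources used here do not say, the counting intervals above would be too narrow.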
